A study of Homo sapiens with 12 samples.

How the data were processed

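Nucleolus-associated domains (NADs), the stretches of chromosomal DNA that co-purify with nucleoli, were profiled in H9 human embryonic stem cells, an established cell line, in 2 pluripotent states. Naive cells were kept in RSeT medium and primed cells in mTeSR medium. Per the labels' protocols, crosslinked cells were broken by sonication, nucleoli were pelleted in buffers of high and then low magnesium, and DNA from the pellet and from whole cells was made into PCR-free libraries with 350 bp fragments read as 150 bp pairs. The 12 libraries form 4 groups of 3: nucleolar DNA and whole-cell DNA, each from naive and from primed cells. Group and replicate were taken from the labels.

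The authors deposited 1 list of NAD regions per cell state, per the labels, each tied to the 6 libraries of that state. A list gives the chromosome, start and end of each region on the hg38 assembly, and no score, height or p-value. BWA, SAMtools 1.10 and SICER are named in the submitters' processing notes, without their roles or order. The window, gap and threshold settings, the way in which 3 replicates became 1 list, and the read depth of the libraries are not given in the sources used here. All region limits in both lists were checked and lie on a 10 kb grid, apart from chromosome ends, so 10 kb is the resolution of every statement about a gene or a boundary. Regions that touch would have been merged before analysis, and neither list held any. Because the depth is unknown, a difference in the number or length of regions between the lists can arise from depth or from the calling settings as well as from the cells.

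With 1 list per state, no value has an error across cultures, and no test compares the cell states across cultures. The tests describe how the regions of these lists lie along the chromosomes. Chromosomes 1 to 22 and X were analysed, 23 in all. Covered sequence was counted in 10 kb bins with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 under Python 3.11.15, and drawings were made with matplotlib 3.10.9.

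The plan, made before the data were examined, was to take assembly gaps of at least 10 kb out of each chromosome. That needs the genome sequence, which was not used here. In its place, stretches of at least 500 kb that held no region of either list and no annotated gene were taken out: 14 stretches of 117.4 Mb in all, mostly centromeres and the short arms of chromosomes 13, 14, 15, 21 and 22. This limit was chosen after the data had been seen, and 2913 Mb were kept. The GC content of NADs, also planned, was not analysed here for want of the sequence.

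Genes came from a table of RefSeq genes on GRCh38.p14, the same assembly as hg38. Of its genes, 679 (153 of them protein-coding) carry coordinates of unplaced or alternate scaffolds and were left out. The remaining 58419 genes include 19821 that code for protein. A gene was counted as lying in a NAD when any part of its body overlapped a region. The table gives no strand, so transcription start sites were not used here.

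Overlap of the lists was tested by rotating the primed list along each chromosome by a random distance, 10000 times, a circular permutation that keeps region lengths and spacing. Two-sided p-values from it cannot fall below 0.0002. The acrocentric chromosomes (13, 14, 15, 21 and 22, whose short arms carry the ribosomal DNA) were compared with the other 18 by an exact two-sided permutation test over all 33649 choices of 5 chromosomes, and its 3 p-values were adjusted together. Gene lists, 27 in number and written before the data were examined, were tested by counting members in NADs and rotating the regions within chromosomes, for each list of NADs and for the naive minus primed count with both lists shifted together. Adjustment was by Benjamini-Hochberg over the 27 lists within each of these 3 tests, at 0.05. Circular permutation allows for the length of genes and the clustering of gene families. An added comparison set each list against 10000 draws of random coding genes of the same chromosome and class of gene density and gene length, a permutation that ignores clustering. Density and length were each split only at the chromosome's median, so very short genes can be set against much longer ones, which touch a region more easily. Other tests over chromosomes used 100000 permutations.

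On simulated data without an effect, made by rotating the real lists, 3.33% of naive, 2.22% of primed and 4.01% of difference tests of gene lists gave an unadjusted p under 0.05, as did 6.67% of 60 overlap tests. When 50% of the uncovered members of a 50-gene list were made covered, the test called 70% of 20 naive and 75% of 20 primed simulations. When 100% were made covered, it called all of them. Moving 2% of primed bins into naive bins was called in 95% of 60 simulations.

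Named genes follow a rule set before the data were examined: every member of the single-copy 8-cell, naive, primed and shared pluripotency lists that lay in NADs of 1 state only; up to 4 members of each other called list with the largest difference in covered share of the gene body, ties by alphabet; the 10 protein-coding genes with the longest naive-only and the 10 with the longest primed-only sequence; and the 5 longest regions of each kind. A gene that 2 parts of the rule name is counted under both. Genes outside the rule are named where a count is small, and those were chosen after their values were seen.

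Alternatives tried were merging across gaps of 10 or 50 kb, leaving out chromosome 19, X or each chromosome in turn, rotating along the whole genome, other definitions of a shared region and of a gene in a NAD, all annotated genes, counting a cluster of genes once, shortening the primed list to the naive covered length, and Fisher's exact test. Length limits of 20 and 100 kb, the midpoint of a gene, chromosomes 13 to 22 alone and keeping the empty stretches were added after the data had been seen.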

Results

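NADs are the parts of the genome found at or near the nucleolus, the site of ribosomal RNA synthesis, and are as a rule rich in silent chromatin. Naive pluripotent cells are held to resemble the epiblast before implantation, and primed cells a later epiblast. How closely the H9 cells kept in RSeT medium did so was not tested here. The title of the study ties nucleolar organisation to LINE1 elements, to the Polycomb complex PRC2 and to repression of the programme of the 8-cell embryo, in which ZSCAN4, LEUTX, DUXA and the TPRX genes are transcribed. The 12 libraries (3 each of nucleolar and whole-cell DNA from naive and from primed cells) entered 1 list of NADs per state, so the values of a list have no replicates and no error across cultures, and their read depth is unknown.

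The first question was how much of the genome lay in NADs in each state. Naive NADs were many and short, and primed NADs fewer and far longer. The naive list held 61750 regions covering 1171 Mb, or 40.2% of the 2913 Mb analysed, and the primed list 29994 regions covering 1327 Mb, or 45.5%, so that the naive list covered 0.883 times the sequence of the primed list. The mean region was 18.97 kb long in naive cells and 44.2 kb in primed cells. The median was 10 kb, a single bin, in both, since 57.7% of naive and 51.3% of primed regions were 1 bin long.

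The contrast lay in the long regions. Regions of at least 100 kb held 5.28% of the naive covered sequence (446 regions) and 55.5% of the primed (1993 regions). The primed list had 119 regions of at least 1 Mb, together 321.7 Mb or 24.2% of its sequence, and the naive list had none. Among the 5 longest primed regions, the first spanned 21.42 Mb of the long arm of chromosome 21 (12960001 to 34380000, hg38) with 98 protein-coding genes, among them the amyloid precursor gene APP, the transcriptional repressor gene BACH1 and a cluster of hair keratin-associated genes such as KRTAP13-1. The second covered 11.76 Mb of chromosome 14 (19610001 to 31370000) with 153 coding genes, including olfactory receptors such as OR4K1 and the ribonuclease genes RNASE1 and RNASE4. The third was 10.74 Mb of chromosome X (72970001 to 83710000) with 35 coding genes, including the chromatin remodeller ATRX and PGK1. The others lay on chromosome 19, from 49320001 to 58617616 with 330 coding genes and from 27240001 to 35660000 with 71.

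None of the 5 longest naive regions, 380 to 520 kb long on chromosomes 21 and 16, overlapped a protein-coding gene, and all 5 lay fully inside primed NADs. The longest was at 9540001 to 10060000 of chromosome 21. The longest naive regions that no primed NAD touched were shorter: 130 kb on chromosome 18 (65310001 to 65440000), 100 kb and over at 3 places on chromosome 13, and 110 kb on chromosome 6 (101480001 to 101590000) inside GRIK2, a kainate receptor gene. The longest primed-only region, 100 kb on chromosome 6 (44060001 to 44160000), held MRPL14, TMEM63B and CAPN11. The other 4 were 80 kb long, and 1 of them, on chromosome 9, held NXNL2.

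The ratio of covered sequence turned with the treatment of gaps: after regions up to 50 kb apart were merged, the naive list covered 78.7% and the primed list 61.4%, a ratio of 1.28. With regions of at least 100 kb alone it was 0.0839, a length limit added after the data had been seen.

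**Figure D1:**
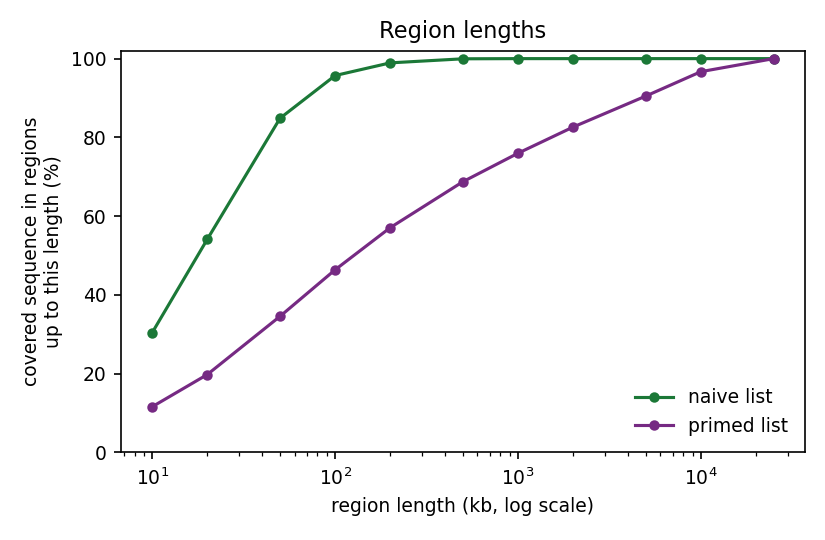
Share of the covered sequence (%, vertical axis) held by regions up to a given length (kb, log scale, horizontal axis) for the naive and the primed list; each point is a length at which the share was read. Regions of up to 50 kb held 84.9% of naive but 34.6% of primed sequence.

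The second question was where along the genome the states shared their NADs. Naive and primed NADs coincided over 645 Mb, which was 55.0% of naive and 48.6% of primed sequence. Circular permutation of the primed list gave 577 Mb on average (central 95%, 563 to 591 Mb), so the lists overlapped 1.12 times as much as rotation gave (p = 0.0002, the smallest that 10000 rotations can give). With the empty stretches kept, this ratio was 1.18. Shorter stretches that neither list could cover were not taken out, so they may add to the excess. The ratio was above 1 on 23 of 23 chromosomes, and past an adjusted p of 0.05 over all possible rotations (exact) on 21 of them; chromosomes 4 (ratio 1.26, adjusted p = 0.0828) and 8 (ratio 1.12, adjusted p = 0.146) were the exceptions. Sequence in naive NADs alone came to 527 Mb and in primed NADs alone to 682 Mb, and 1059 Mb lay in neither. By number, 53.2% of naive and 56.4% of primed regions touched the other list, and 12.9% and 26.5% did when 50% of both regions had to coincide.

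Long primed regions were dense in short naive ones. Inside primed regions of at least 1 Mb, naive NADs covered 62.1% ± 6.29 of the sequence (SD over 23 chromosomes), against 40.1% ± 5.71 outside them, and the share was higher inside on 23 of 23 chromosomes (permutation test, two-sided p = 2e-05, the smallest it can give). The chromosome 21 region above was 81.1% covered by naive NADs, and the chromosome 19 region that ends at the chromosome's tip was 53.0% covered.

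The third question was how the chromosomes differed, and whether the chromosomes that carry ribosomal DNA had the most sequence in NADs. In primed cells the share in NADs ran from 18.9% of chromosome 4 to 97.3% of chromosome 19, with 94.5% of chromosome 20, 92.1% of 21, 91.4% of 22 and 80.9% of 16. In naive cells the range was narrower, from 33.0% of chromosome 2 to 69.2% of chromosome 21. Chromosome 19, the most gene-dense chromosome, with 25.0 coding genes per Mb, was at 51.6% in naive cells. Naive shares were higher than primed ones on 7 of the 23 chromosomes, by 14.6 percentage points on chromosome 4 and 14.01 on chromosome 13.

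The 5 acrocentric chromosomes had more sequence in naive NADs than the other 18, 54.3% ± 8.90 against 40.7% ± 7.01 (SD over chromosomes, a difference of 13.6 percentage points, exact permutation p = 0.00175, two-sided, adjusted p = 0.00526). In primed cells the means were 71.9% ± 24.1 and 49.8% ± 24.3 (22.1 points, exact permutation p = 0.0884, adjusted p = 0.133). Chromosome 13 was at 32.8% and the other 4 at 68.5% or more. The primed difference turned to -7.72 points among chromosomes 13 to 22 (exact permutation p = 0.571). Counted by number, it was -3.13 regions per Mb (exact permutation p = 0.0805). The primed difference in share was 10.02 points with empty stretches kept (exact permutation p = 0.395). Without chromosome 19 it was 24.9 points (exact permutation p = 0.0428, not adjusted over the 3 tests). The naive minus primed share differed by -8.50 points (exact permutation p = 0.369), which turned to 13.3 points among chromosomes 13 to 22 (exact permutation p = 0.278). By number the difference was 2.33 regions per Mb, and none of these passed. The naive call ended when the empty stretches, which include the acrocentric short arms, were kept (4.81 points, exact permutation p = 0.198) and when the comparison stayed among chromosomes 13 to 22 (5.54 points, exact permutation p = 0.190). Counted by number, the naive difference was -0.803 regions per Mb. Region number does not measure covered share, because it falls where regions join. Chromosome 21 had the highest naive share, 69.2%, and the fewest naive regions per Mb, 14.9.

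Shorter chromosomes had more of their sequence in NADs in both states: the share fell with chromosome length in naive cells (Pearson's r = -0.847, p = 1e-05; Spearman's rho = -0.884, p = 1e-05) and in primed cells (r = -0.809, p = 2e-05; rho = -0.847, p = 1e-05; permutation tests over 23 chromosomes, 1e-05 being the smallest p they can give). Without chromosomes 1 and 2, the farthest from the median length, r was -0.843 and -0.844. The share followed coding genes per Mb in primed cells (r = 0.581, p = 0.00071; rho = 0.609, p = 0.0026; r = 0.535 without chromosomes 17 and 19) and did not pass the test in naive cells (r = 0.253, p = 0.23; rho = 0.328, p = 0.13). Across chromosomes the naive and primed shares rose together (r = 0.863, p = 1e-05; rho = 0.881, p = 1e-05; r = 0.875 without chromosomes 19 and 20). The adjusted p over these 5 relations stayed under 0.05 for the 4 that passed, 0.00089 and 0.0032 for primed gene density.

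**Figure D2:**
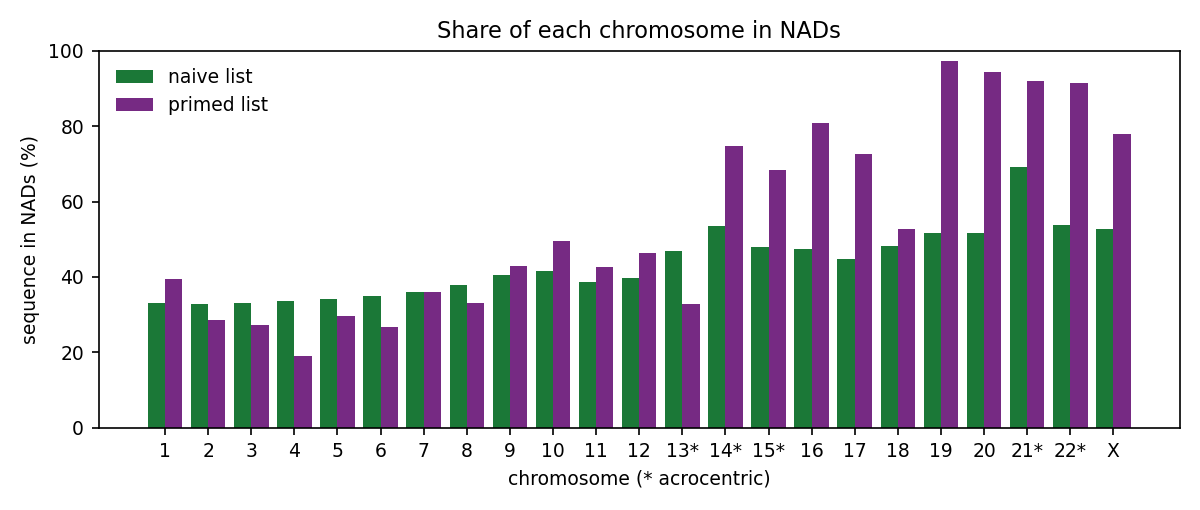
Percent of each chromosome's analysed sequence (vertical axis) in naive (green) and primed (purple) NADs for chromosomes 1 to 22 and X (horizontal axis, acrocentric ones starred); each bar is 1 value without replicates. The primed bars reach 97.3% on chromosome 19 and 94.5% on chromosome 20 and fall to 18.9% on chromosome 4.

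The fourth question was which genes lay in NADs, first those of the 8-cell programme. Of 30 single-copy 8-cell genes, 26 lay in primed NADs and 21 in naive NADs, 20 of them in both. Circular permutation gave 20.9 and 19.7 on average, and neither list passed the test (primed p = 0.0252, adjusted p = 0.0756; naive adjusted p = 1), nor did the difference (adjusted p = 0.663). In primed NADs the single-copy genes did not pass against random coding genes matched on chromosome, gene density and gene length. The 26 members compared with a matched mean of 24.0 (permutation within classes, adjusted p = 0.692). All 9 on chromosome 19 were in NADs of both states: MBD3L2, LEUTX, ZNF296, TPRX1, TPRX2, DPRX, ZSCAN5B, DUXA and ZSCAN4. Elsewhere, 17 of 21 were in primed and 12 of 21 in naive NADs. ZSCAN4, a telomere and genome stability factor of early embryos (chromosome 19, 57651476 to 57679152), had 100% of its body in primed and 69.2% in naive NADs, and the paired-like homeobox gene DUXA (57154021 to 57167485) 100% and 44.4%. TPRX1 and LEUTX, homeobox genes of the same programme, had 100% in both.

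In primed NADs only were ARGFX (53.2% of the gene body), the germline cyclin CCNA1 (25.3%), DUXB (19.3%), FAM151A (75.4%), the histone variant H3Y1 (100%) and TRIM43 (100%). In naive NADs only was the phosphatase gene ALPG (18.4%). KDM4E, KHDC1L and RFPL4B lay in neither. Of 70 members of multicopy 8-cell families, such as PRAMEF, TRIM49 and DUX4 genes, 49 were in primed and 42 in naive NADs, against permutation means of 30.96 and 33.7 (adjusted p = 0.289 and 0.636). These families lay near the means of matched random coding genes, 50.4 in primed and 41.9 in naive NADs. Their placement is uncertain because reads of near-identical copies cannot be placed uniquely, and the same holds for TRIM43, H3Y1, ALPG and MBD3L2, which have close relatives.

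**Figure D3:**
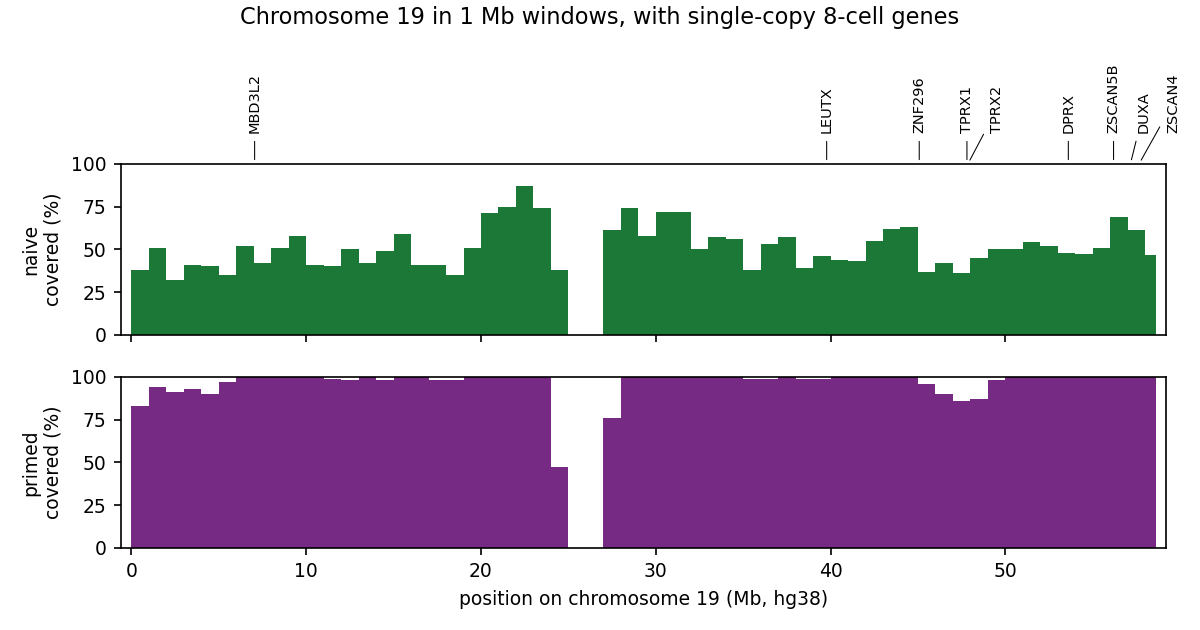
Percent of sequence in naive (upper) and primed (lower) NADs in 1 Mb windows of chromosome 19 (position in Mb, hg38), with the 9 single-copy 8-cell genes marked above; the blank at the centre is a stretch without regions or genes. Primed NADs cover 97.3% of the chromosome and naive NADs 51.6%.

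Of the 3 lists of pluripotency genes, those of shared and of primed-state genes were called in primed NADs and that of naive-state genes was not. Neither of the called lists exceeded matched random coding genes (9 against 7.58 and 19 against 16.2, permutation within classes, adjusted p = 0.706 and 0.418). Of 10 genes shared by the naive and primed states, 9 were in primed NADs (permutation mean 5.06, adjusted p = 0.0396) and 4 in naive NADs (5.89, adjusted p = 0.782), and the difference of -5 members passed the test (permutation mean 0.833, adjusted p = 0.0432). The members in primed NADs only were NANOG, a core transcription factor of pluripotency (chromosome 12, 7789402 to 7799146, 100% of the gene body), the RNA-binding regulator LIN28A (chromosome 1, 26410817 to 26429728, 100%), the NODAL co-receptor CRIPTO (100%), the telomerase gene TERT (83.7%) and DPPA4 (71.4%). POU5F1, SOX2, SALL4 and UTF1 were in NADs of both states, and L1TD1 in neither. The primed call of this list was lost under 3 of 13 alternatives (adjusted p up to 1, Fisher's exact test), and its difference under 6 of 13 (permutation, adjusted p up to 0.444).

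Of 22 genes of the primed state, 19 were in primed NADs (permutation mean 13.8, adjusted p = 0.0396) and 16 in naive NADs (15.8, adjusted p = 1). The difference of -3 did not pass (permutation mean 1.97, adjusted p = 0.282). CYTL1, ZIC2 (both 100%), the sialomucin PODXL (52.8%), the ERK phosphatase DUSP6 (47.5%) and the neural factor SOX11 (15.4%) were in primed NADs only, FGF2 (25.5%) and the WNT receptor FZD7 (100%) in naive NADs only, 14 in both and 1 in neither; the primed call was lost under 6 of 13 alternatives (adjusted p up to 0.919). Of 25 genes of the naive state, 16 were in primed and 15 in naive NADs, with permutation means of 14.3 and 16.7 and no call (adjusted p = 0.752 and 0.829). In naive NADs only were DPPA2 (71.3%), KHDC3L (100%), KLF5 (44.3%), PRDM14 (51.0%) and ALPG, and in primed NADs only ARGFX, DPPA3 (100%), DPPA4, FGF4 (100%), TRIM60 (82.1%) and ZFP42 (100%); 10 lay in both and 4 in neither. DPPA2 and DPPA4, neighbours on chromosome 3 (109293788 to 109316517 and 109326144 to 109339636), thus fell in different lists. The naive-only sequence in DPPA2 was 16.2 kb long and the primed-only sequence in DPPA4 9.64 kb. On a 10 kb grid, this contrast rests on very few bins.

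Among developmental and structural gene groups, primed NADs held 113 of 157 Polycomb-target regulators (permutation mean 89.3, adjusted p = 0.0419) and naive NADs 92, against a mean of 92.0 (adjusted p = 1); the primed call was lost under 3 of 13 alternatives and reversed with Fisher's exact test (-15.6 members against the number from all other genes, adjusted p = 0.00722). The primed count did not exceed matched random coding genes either (113 against 115, permutation within classes, adjusted p = 1). For the Polycomb targets, the difference of -21 did not pass (permutation mean 2.79, adjusted p = 0.0994). Their largest differences included CDX2, DLX1 and DLX6, homeobox genes of trophoblast, forebrain and limb, with 100% of the gene body in naive NADs and 0 in primed, and DLX3, with the reverse. C2H2 zinc finger genes outside chromosome 19 lay in primed NADs for 262 of 294 members (permutation mean 200.1, adjusted p = 0.0054) and in naive NADs for 239 (229, adjusted p = 0.636). The difference of -23 passed the test (permutation mean 29.2, adjusted p = 0.0054), a call lost with Fisher's exact test (adjusted p = 0.281). ZFP36L2, ZFP42, ZFP92 and ZNF174 had 100% in primed and 0 in naive NADs; ZFP36L2, an RNA-binding protein, entered the list by its name. On chromosome 19 all 262 zinc finger genes were in primed and 234 in naive NADs, against permutation means of 259.6 and 224.6 (adjusted p = 0.887 and 0.636). Rotations also reached all 262 in primed NADs, so the primed test could not call an excess.

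Olfactory receptors and histone genes were the groups called in naive NADs. Of 389 olfactory receptors, 287 were in naive NADs (permutation mean 198.5, adjusted p = 0.0027) and 322 in primed NADs (206.7, adjusted p = 0.0054); the difference did not pass (adjusted p = 0.748). The primed call was lost with gaps of 50 kb merged and with Fisher's exact test (adjusted p up to 0.854). OR10G4, OR10G9 and OR10S1 had 100% in naive NADs alone and OR10A4 100% in primed NADs alone. Of 70 replication-dependent histone genes, 59 were in naive NADs (permutation mean 25.6, adjusted p = 0.0027) and 49 in primed NADs (21.3, adjusted p = 0.289). For histones, too, the difference of 10 members did not pass (permutation mean 4.38, adjusted p = 0.870). In the main cluster on chromosome 6, H1-1 and H1-3 were in naive NADs alone and H1-4 and H2AC13 in primed NADs alone. Against matched random genes, both lists had more members in naive NADs (287 against 239 and 59 against 42.6, permutation within classes, adjusted p = 0.0052 for each), but not in primed NADs (322 against 330.3 and 49 against 55.6, adjusted p = 0.418 and 0.137). Both naive calls ended when members within 1 Mb of each other were counted as 1 cluster and with Fisher's exact test, where the olfactory receptor value turned to -12.1 members (adjusted p = 0.199), and that of histones also with gaps of 50 kb merged. Receptors and histones of near-identical sequence are uncertain.

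Keratins and keratin-associated proteins lay almost wholly in primed NADs, 146 of 149 (permutation mean 114.8, adjusted p = 0.0401), and 90 lay in naive NADs (89.9, adjusted p = 1). The epidermal keratins KRT14, KRT15 and KRT17 and the corneal keratin KRT12, all on chromosome 17, had 100% in primed and 0 in naive NADs. This call was lost when gaps of 10 or 50 kb were merged, with the midpoint of the gene and when clusters were counted once (permutation, adjusted p up to 0.311). The naive minus primed difference of -56 did not pass (permutation mean -24.9, adjusted p = 0.150).

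Housekeeping genes, active in both states, were in primed NADs as well. Ribosomal protein genes were in primed NADs for 66 of 85 members (permutation mean 51.3, adjusted p = 0.0054) and in naive NADs for 59 (46.5, adjusted p = 0.0558); FAU, RPL13, RPL18 and RPL19 had 100% in primed and 0 in naive NADs. The primed value turned to -3.56 members with Fisher's exact test (adjusted p = 0.514), and matched random genes gave 66.8 (permutation within classes, adjusted p = 1). Proteasome genes were in primed NADs for 44 of 48 members (34.6, adjusted p = 0.0149) and in naive NADs for 32 (35.0, adjusted p = 0.782), and the difference of -12 passed (permutation mean 0.373, adjusted p = 0.0189), a call lost under 4 of 13 alternatives. The primed call was lost with the midpoint of the gene and with Fisher's exact test (adjusted p up to 0.212), and the count did not pass against matched random genes (44 against 41.3, permutation within classes, adjusted p = 0.551). PSMA7, PSMB10 and PSMB3 had 100% in primed NADs alone, and PSMA4 in naive NADs alone. Cytochrome P450 and UGT genes of drug and steroid metabolism were called in the difference only. They had 58 of 89 members in naive and 68 in primed NADs (difference of -10, permutation mean 11.0, adjusted p = 0.0432). That call was lost under 10 of 13 alternatives. CYP11B1, CYP11B2, CYP2A6 and CYP2A13 had 100% in primed and 0 in naive NADs, and each has a close relative beside it.

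In all, 2 of 27 gene lists were called in naive NADs, 8 in primed NADs, all of them with more members in NADs than under permutation, and 4 in the difference, all with a naive minus primed count below its permutation mean. Without adjustment, 6, 9 and 6 lists had p under 0.05. Of 19821 protein-coding genes, 12927 (65.2%) lay in NADs of both states, 2301 in naive NADs only, 3291 in primed NADs only and 1302 in neither. Primed NADs touched 16218 coding genes against a permutation mean of 13764 (p = 0.0002, the smallest possible) and naive NADs 15228 against 15199 (p = 0.751), a comparison added after the data had been seen. Called bins held more coding genes per Mb than uncalled ones on 19 of 23 chromosomes in primed cells and on 4 of 23 in naive cells.

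**Figure D4:**
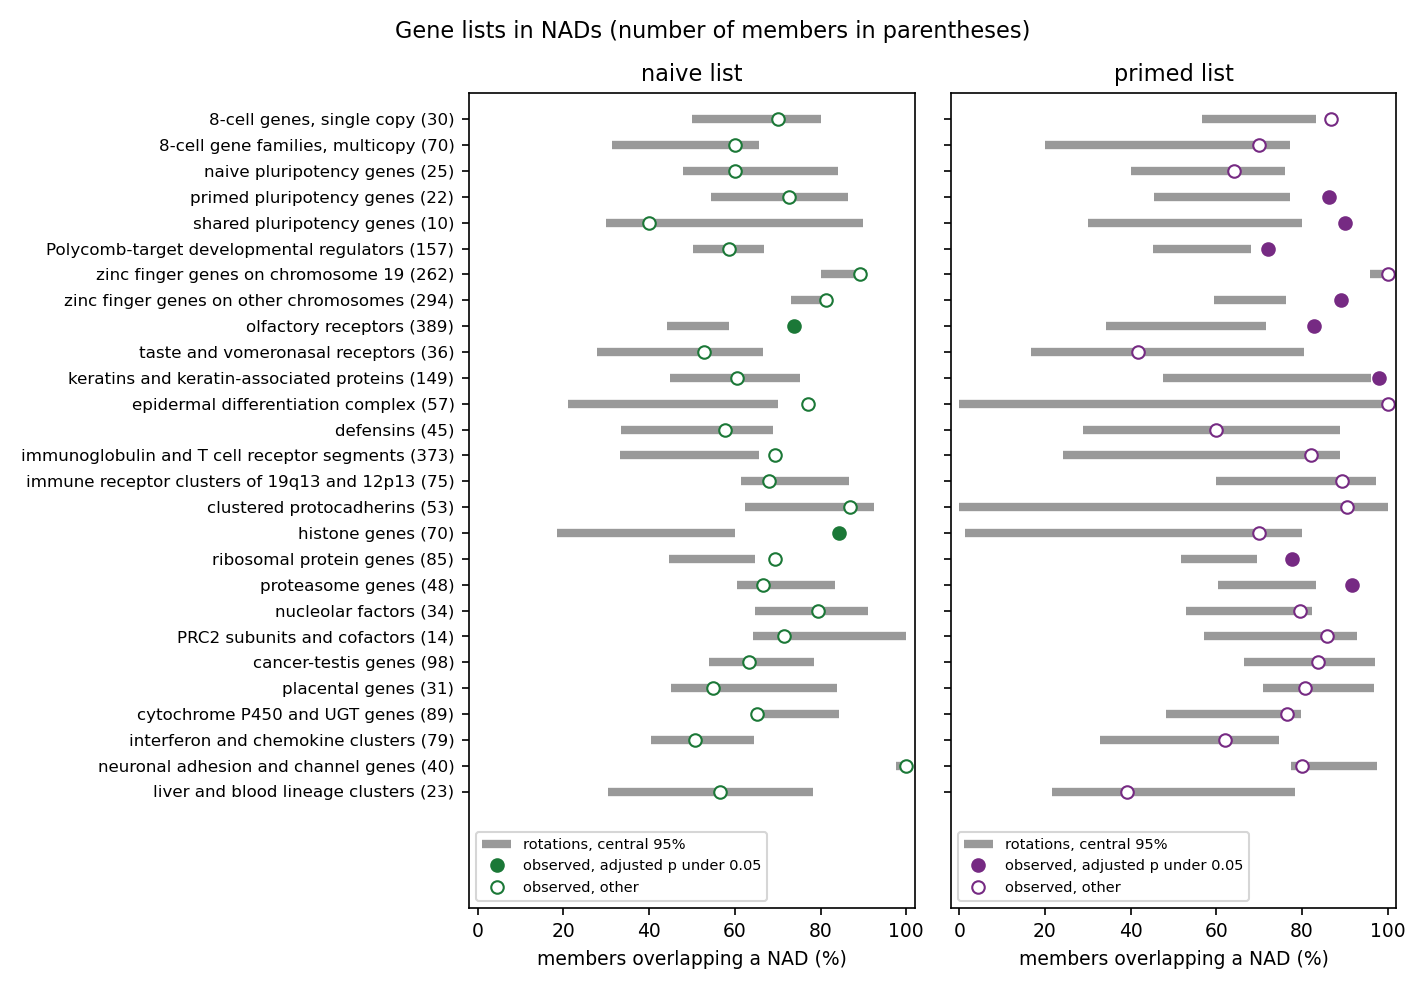
Members of each of the 27 gene lists that overlap a NAD (%, horizontal axis) in the naive (left) and the primed list (right); circles are the observed shares, filled where the adjusted p is under 0.05, and grey bars the central 95% of 10000 rotations. Filled circles mark 2 lists in naive and 8 in primed NADs.

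Long genes showed the largest amounts of sequence specific to 1 state. Ranking by length of sequence favours long genes by construction. Naive-only sequence was longest in PTPRD (1076 kb of its 2299 kb), ROBO2 (800 kb), CNTNAP2 (763 kb), PCDH15, DLG2, CSMD1, LRP1B, CCSER1, CNTN5 and CTNNA3 (650 kb). PTPRD, a receptor phosphatase gene (chromosome 9, 8314246 to 10613002), had 47.2% of its body in naive and 1.87% in primed NADs, and LRP1B, a lipoprotein receptor gene, 36.8% and 0. Primed-only sequence was longest in the splicing factor gene RBFOX1 (920 kb; 90.7% in primed and 59.2% in naive NADs), MACROD2 (also 920 kb), AGBL4 (807 kb), KAZN, PTPRN2, DLGAP2, AUTS2, DPP6, EYS and CTNNA2 (525 kb). All 10 of these overlapped NADs of both states.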

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

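The test over all protein-coding genes was chosen only after the result was seen.

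A difference between the cell states marked 4 gene lists, each by the circular permutation test of the difference itself. The naive minus primed number of members in NADs was -5 of 10 for shared pluripotency genes (NANOG, LIN28A, CRIPTO, TERT and DPPA4), -23 of 294 for zinc finger genes outside chromosome 19, -12 of 48 for proteasome genes and -10 of 89 for cytochrome P450 and UGT genes. Under permutation the means were 0.833, 29.2, 0.373 and 11.0. The difference over all protein-coding genes ran the same way, -990 against a permutation mean of 1436 (p = 0.0002, the smallest possible), so these 4 lists moved in the direction of coding genes at large. The test compares 2 lists of regions, not cultures.

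The pattern weighed here is that 8 gene lists, among them silent olfactory receptors and active ribosomal protein and proteasome genes, lay in primed NADs more often than under permutation. A technical or general explanation is that gene-dense sequence as such was called in the primed list, whatever the genes do. Against random coding genes matched on chromosome, gene density and gene length (a permutation within these classes), 2 of the 8 lists still had more members in primed NADs, zinc finger genes outside chromosome 19 (262 against 238, adjusted p = 0.00173) and keratins (146 against 138, adjusted p = 0.0139). The other 6 did not, so gene density may account for those. Length was matched only as above or below the chromosome's median, so the test cannot separate gene density from remaining differences in gene length. In the same test, among lists that rotation did not call, the epidermal differentiation complex lay above matched genes (57 against 51.9, adjusted p = 0.0305), and taste and vomeronasal receptors (15 against 29.1, 0.00173), interferon and chemokine genes (49 against 62.5, 0.00173), defensins (27 against 35.5, 0.0114) and liver and blood genes (9 against 16.0, 0.0114) lay below them (permutation within classes), so the matched classes do not set the share of every list. This test ignores the clustering of families, which makes its p-values too small, so gene density and a preference for particular genes cannot be told apart for the 8 lists, and a biological difference between the states was not tested.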

How the results depend on the processing

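Tests at 20 and 100 kb, with the gene midpoint, with empty stretches kept and on chromosomes 13 to 22 alone were chosen only after the result was seen. No paired analysis was possible because the region lists carry no replicate numbers. A limit at the median length removed nothing, as both medians were 10 kb, and a stricter threshold and start sites were not run for want of a score and a strand. The unknown read depth and calling settings limit every comparison of region number and length.

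The ratio of covered sequence was 0.883, and 0.969 after merging across 10 kb, 1.28 across 50 kb (reversed, because more of the many short naive gaps close), 0.904 on autosomes, 0.898 without chromosome 19, 0.695 with regions of at least 20 kb, 0.0839 with at least 100 kb, and 0.858 to 0.904 without each chromosome in turn. Overlap over its permutation mean stayed between 1.05 and 1.696, with p = 0.0002 in each alternative. With 50% of a region covered, 50.6% of naive and 42.7% of primed regions were shared, and 12.9% and 26.5% with 50% of both. The naive acrocentric difference, 13.6 points, was 4.81 with empty stretches kept and 5.54 on chromosomes 13 to 22. The primed one, 22.1, was 24.9 without chromosome 19 (exact permutation p = 0.0428), 10.02 with empty stretches kept and -7.72 on chromosomes 13 to 22. Keeping the empty stretches adds sequence without regions, including the acrocentric short arms, so it lowers the shares of those chromosomes by construction. The cause of the other changes in share was not tested. By number the differences were -0.803 (naive) and -3.13 (primed) regions per Mb, a count that falls where regions join and does not measure covered share.

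The naive count of called gene lists, 2, was 1 with 50 kb merged, 4 with rotation over the whole genome, with empty stretches kept and with 50% of the gene body covered, 0 with clusters counted once, 5 with all annotated genes and 13 with Fisher's exact test, of which 2 were higher and 0 were among the 2 called. The primed count, 8, was 4 with 50 kb merged, 4 with the gene midpoint and 11 with Fisher's exact test, of which 4 were higher and 3 were among the 8. Those 3 include the Polycomb targets, which Fisher's test called in the reverse direction. The difference count, 4, was 2 with 50% of the body, 1 with the midpoint, 2 with all annotated genes and 7 with Fisher's exact test, of which 2 were higher and 0 were among the 4 called. In the difference, 1 list was called higher with 50% of the body, with the primed list cut to the naive covered length and with regions of at least 20 kb. The cause was not tested, except that Fisher's test by construction ignores gene length and clustering. Under it, members above the number from all other genes were reversed to -11.8 (naive) and -8.30 (primed) for multicopy 8-cell families, -15.6 for Polycomb targets, -9.84 for defensins, -8.30 for histones, -3.56 for ribosomal proteins and -15.7 for interferons and chemokines in primed NADs; to -12.1 for olfactory receptors, -8.67 for taste receptors, -24.7 for keratins, -8.59 for defensins and -27.6 for immunoglobulin and T cell receptor segments in naive NADs; and to -15.1 for chromosome 19 zinc fingers and -28.4 for immunoglobulin and T cell receptor segments in the difference. Over all settings, called lists kept their call 134 times, lost it 45 times and reversed 3 times; lists not called stayed so 809 times, gained a call 45 times and reversed 11 times. The primed call of zinc finger genes outside chromosome 19 held in 13 of 13 alternatives.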

Other observations

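All tests in this part except those of the 27 gene lists were chosen only after the result was seen; the acrocentric comparison was planned, and its use as an explanation was not.

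Gene groups with roles in the nucleolus or in Polycomb repression did not pass the test in either state. Of 34 genes of ribosome synthesis, 27 lay in naive and 27 in primed NADs (permutation means 26.4 and 22.9, adjusted p = 1 and 0.289). NPM1, which encodes a major nucleolar protein, was in primed NADs only, and NCL, which encodes nucleolin, in neither. Of 14 genes of PRC2 and its cofactors, 10 were in naive and 12 in primed NADs (permutation means 11.5 and 10.5, adjusted p = 0.782 and 0.732). Of these 14 genes, 2 lay in naive NADs only and 4 in primed NADs only. The catalytic subunit gene EZH2 and its partner EED were in naive NADs only and EZH1 in primed NADs only, while SUZ12 and JARID2 were in both. TRIM28, a corepressor of repeat elements on chromosome 19, had 100% of its body in NADs of both states. These genes were picked after their values were seen.

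Of the other gene lists of tissue-specific clusters, apart from the olfactory receptors and keratins already described, none passed the adjusted circular permutation test of membership in either state. In primed NADs, 5 of them differed from matched random genes, in a test that ignores clustering and matches length only coarsely. The epidermal differentiation complex lay above, and taste and vomeronasal receptors, interferon and chemokine genes, defensins, and liver and blood genes below. The epidermal differentiation complex had 57 of 57 members in primed and 44 in naive NADs (permutation means 25.2 and 24.8, adjusted p = 0.289 and 0.0702), and 306 and 259 of 373 immunoglobulin and T cell receptor segments lay in primed and naive NADs (236.3 and 179.7, adjusted p = 0.340 and 0.0702). Clustered protocadherins had 48 and 46 of 53 members in primed and naive NADs (permutation, adjusted p = 0.710 and 0.782), immune receptors of 19q13 and 12p13 had 67 and 51 of 75 (0.944 and 0.782), cancer-testis genes 82 and 62 of 98 (1 and 0.825), placental genes 25 and 17 of 31 (0.732 and 0.782), defensins 27 and 26 of 45 (0.867 and 0.825), taste and vomeronasal receptors 15 and 19 of 36 (0.887 and 0.825), interferon and chemokine genes 49 and 40 of 79 (0.710 and 1), and liver and blood genes 9 and 13 of 23 (0.732 and 1). All 40 long neuronal adhesion and channel genes touched naive NADs, where permutation gave 39.9, and 32 touched primed NADs (35.5, adjusted p = 0.289).

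Among genes of small RNAs, 338 of 429 tRNA genes lay in primed NADs and 239 in naive NADs (permutation means 184.0 and 164.5, adjusted p over 9 gene classes = 0.0021 and 0.009). MicroRNA genes lay in naive NADs less often than under permutation, 726 of 1911 against 812 (adjusted p = 0.0126), and in primed NADs more often, 1183 against 1033 (adjusted p = 0.00036). Genes of snRNAs lay more often in both, 80 of 149 in naive and 112 in primed NADs (permutation means 62.4 and 86.1, adjusted p = 0.0446 and 0.00643), and those of snoRNAs in primed NADs, 719 of 1190 against 602 (adjusted p = 0.00036), with 532 against 497 in naive NADs (adjusted p = 0.309). Outside the small RNAs, 11268 of 17904 long non-coding RNA genes lay in naive NADs, fewer than the permutation mean of 11469 (adjusted p = 0.0131), and 11577 in primed NADs, more than 10476 (adjusted p = 0.00036), while pseudogenes lay above it in both (6756 of 15048 against 6535 and 8010 against 7375, permutation, adjusted p = 0.0099 and 0.00036). Of the 17 genes of 5S ribosomal RNA on chromosome 1, none was in naive and 7 were in primed NADs (permutation, adjusted p = 0.631 and 0.993). The 3 annotated copies of 45S ribosomal RNA on chromosome 21 were in NADs of both states. Copies of ribosomal RNA genes are near-identical, so these placements are uncertain, and the same holds for tRNA and snRNA genes with close copies. Matched random genes and clusters counted once were not tried for these gene classes. Protein-coding genes at large also lay in primed NADs more often than under permutation (16218 against 13764). The outermost 1 Mb at 41 chromosome ends was 72.9% ± 20.8 (SD over ends) in primed NADs, above its own chromosome's share at 33 ends, and 41.7% ± 11.03 in naive NADs, above it at 17; the short-arm ends of the 5 acrocentric chromosomes lie in empty stretches and were left out.

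Naive regions were short and primed regions long, and 2 explanations from the calling were set against this. If a larger share of the chromosome merely let primed bins touch, primed regions would be no longer where the primed list covers less. The mean primed region was longer on 7 of 7 such chromosomes (on chromosome 4, 26.5 kb at 18.9% covered against 16.7 kb at 33.6%). This speaks only to the share of whole chromosomes. Bins touch according to the share near them. Shuffling primed bins within 1 Mb windows, which keeps that share, gave 32177 regions on average against 29985. Crowding of primed bins within such windows is thus not excluded as a source of the longer regions. Suppose naive bins were called independently of their neighbours, at an even rate within each 1 Mb window. Shuffling them within windows would then leave the number of regions in place. The count was 61743 once empty stretches were taken out, which joins regions on either side of a stretch. That was 95.3% of the shuffled mean and below all 20 shuffles (64611 to 65051). Independent calls at a rate that varies within windows could give the same, so independence is not excluded. The criterion, a count below every shuffle, replaced, once the value was seen, a bound of 95% under which it would have counted for independence. Primed regions were about as close to shuffled ones within windows (93.2%), so in both lists part of the fine structure may be noise or thin sequencing, and the lists lay far apart in shuffles over whole chromosomes, where naive regions were 90.3% and primed regions 51.2% of the shuffled number. Differences in depth or in calling between the lists were not tested, and a biological difference between the states, with scattered contacts in naive cells, stays open as well.

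Primed shares ranged widely between chromosomes. Recovery that follows gene density, whether by GC-linked bias in the nucleolar fraction or by its chromatin, is a candidate explanation: rho with coding genes per Mb was 0.609 (permutation p = 0.0026), and called bins were gene-richer on 19 of 23 chromosomes. Nearness to the ribosomal DNA of the acrocentric short arms cannot be told apart from other causes, because the difference of 22.1 points missed the threshold (exact permutation p = 0.0884), passed without chromosome 19 (24.9, p = 0.0428) and turned to -7.72 among chromosomes 13 to 22, and the non-acrocentric chromosomes 19 and 20 had the highest shares. Chromosome length, with rho = -0.847, was a closer correlate. GC content was not analysed here, and a biological difference was not tested.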
